A study of Homo sapiens with 2 samples.

How the data were processed

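Small RNA was sequenced after immunoprecipitation of FLAG-tagged AGO2 or AGO3 from HEK293 cells, with 1 library per protein. Per the labels, the cells were lysed with NP40, the tag was captured on magnetic beads, the RNA was released with proteinase K and phenol and size-selected, and custom adapters were ligated to both ends before reverse transcription. Per the labels, the 5′ adapter adds a pair of random bases to each read, and the 3′ adapter sequence differs between the AGO2 and the AGO3 library, so adapter and protein change together.

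The deposited tables hold 1 raw count per miRNA precursor and library, per the file headers with the reads in all, mapped and unmapped. The counts are whole numbers that sum to the mapped reads, each copy of a miRNA has its own entry, and the arms of a hairpin are not named. Bowtie2 2.1.0 and build hg19 are named in the submitters' processing notes, without their role. The miRBase release, the treatment of the random bases, the mismatches allowed, the use of strand and the treatment of reads that match several precursors are not given in the sources used here. A deposited genome-wide list of read stacks gives the count of reads in each stack, its position, annotation and number of edits, and a score that per the file headers and fields is the entropy of its read positions; the score was not used here. In that list the libraries are pooled, and which ones were pooled is not given in the sources used here.

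From the counts, the log2 ratio of AGO3 over AGO2 was computed for each precursor as the ratio of its shares of all precursor counts, with a pseudocount of 0.5 scaled to the library size. Its interval came from the exact (Clopper-Pearson) 95% interval of the AGO3 part of the precursor's counts. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 counts, or 8.61e-05% of the AGO2 and 9.82e-05% of the AGO3 counts. Precursors with at least 100 counts over both libraries were compared; they hold 99.8% of the counts of all 1038. With 1 library per group no test was made, and a precursor was counted as apart when its ratio was at least 2-fold. The procedure was tested on simulated counts of the AGO3 against AGO2 comparison. It called 4 of 324 unchanged precursors and all 41 of those simulated at a log2 change of 2 and all 41 at a log2 change of 3. Both simulated libraries came from the same profile with counting error only, and no change near 2-fold was simulated. The result thus checks the computation and gives no rate of false calls between real libraries.

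Groups, comparisons, lists and the rule for named precursors were fixed before the data were examined. Precursors named are the 10 most abundant by mean CPM, the 10 highest and the 10 lowest log2 ratios among those with at least 100 counts, up to 4 of the most abundant members of each list with at least 100 counts, and mir-451a. Stacks named are the 10 with the most reads outside miRNA precursors. Other precursors, the copies in the closing part and small classes of stacks (SCARNA15, the vault RNAs) were chosen after their values were seen. The lists were let-7, miR-17~92 with paralogues, miR-15/16, the HOX miRNAs 10 and 196, miR-30, miR-221/222, miR-181, miR-29, miR-23/27/24, pluripotency, the placental cluster of chromosome 19, DLK1-DIO3, other cell types, Dicer-independent (miR-451), Drosha-independent, mirtrons, snoRNA-derived, tRNA-like and rRNA-like, 19 in all. The median log2 ratio of a list was given as its percentile among 10000 random lists of the same size. In these each member was replaced by 1 of the 20 precursors nearest in abundance, the member itself included. Other members of the list could also be drawn, and a precursor could be drawn more than once, so random lists can partly hold the list itself. Planned measures of arm use, of the let-7a passenger strand and of passenger strands in general could not be made, because the counts cover both arms together.

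Stacks were put in 1 class each, in the order miRNA precursor, mitochondrial, tRNA, rRNA, snoRNA or scaRNA, snRNA, vault RNA, Y or other scRNA, 7SL, exon, intron, antisense to a gene, and the rest, from the annotation in the stack list. A precursor was taken to share reads when it has another numbered copy or a partner on the opposite strand. Such a partner could be found only for precursors named in a stack. Lettered relatives with the same main miRNA, such as mir-365a and mir-365b, are outside this rule. Alternatives covered other scalings (median of ratios and TMM from edgeR 4.0.16), other count minimums, another pseudocount and other choices of stacks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.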

Results

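Small RNAs bound to Argonaute were measured in HEK293 cells, a human embryonic kidney line, that expressed either FLAG-tagged AGO2 or FLAG-tagged AGO3. Argonaute proteins hold miRNAs of about the length that Dicer cuts and carry them to their targets, and AGO2 is the member best known for slicing target RNA. Each protein was pulled down with beads against the tag, and the small RNA in it was sequenced. There was 1 AGO2 library and 1 AGO3 library, so no difference between them has a replicate check, no test between the groups was made and no p-value is given. The AGO2 library held 6674064 reads, of which 3485257 (52.2%) were counted on miRNA precursors. The AGO3 library held 4667236 reads, of which 3055417 (65.5%) were counted on them. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only. Precursors are written without the species prefix, each count covers both arms of the hairpin, and positions are those of the read stacks over the precursor in build hg19.

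The first comparison asked which miRNAs were held at different levels by AGO3 and AGO2. Large differences towards AGO3 were found in mir-625 and mir-486, and large differences towards AGO2 in mir-3676 and mir-19b-1. The count of mir-625, whose hairpin lies in the FUT8 gene, was 1163 in AGO2 and 9638 in AGO3, a log2 ratio of 3.24 (interval 3.15 to 3.33) after scaling to the counts of each library. For mir-486, a miRNA abundant in red blood cell precursors and muscle, the counts were 672 and 5745, a log2 ratio of 3.28 (3.17 to 3.40). For mir-3676, an entry since attributed to a tRNA and therefore uncertain as a miRNA, the counts were 3719 and 564, a log2 ratio of −2.53 (−2.66 to −2.40). For mir-19b-1, a member of the miR-17~92 cluster at chr13:92003432-92003642, the counts were 19769 and 4443, a log2 ratio of −1.96 (−2.01 to −1.92). No pooled stack carried the name of mir-625, mir-486 or mir-3676. Their counts could therefore not be set against stack reads, and a partner on the opposite strand could not be looked for.

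Among precursors with at least 100 counts over both libraries, 65 were at least 2-fold higher in AGO3 and 36 were at least 2-fold lower, 24.6% of them in all. The remaining 310 were less than 2-fold apart, and the median log2 ratio was 0.08 with an SD across precursors of 1.02. The precursors at least 2-fold apart held 15.5% of the AGO2 counts and 18.7% of the AGO3 counts. The counting interval lay wholly beyond 2-fold for 53 of the higher and 20 of the lower precursors. It excluded equal shares for 348 of these precursors (84.7%).

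The highest log2 ratio was that of mir-642b at 5.22 (4.68 to 5.89), from 25 and 834 counts, followed by mir-642a at 4.13 (3.78 to 4.53), from 64 and 992 counts. Both hairpins lie on opposite strands of the same stretch in the GIPR gene (chr19:46178199-46178258), and a read of one can be taken for the other unless strand is used in counting, which is not given in the sources used here. In the pooled stacks, which keep strand, mir-642b had 41 reads and mir-642a 4353, so that the ratio of mir-642b is uncertain as its own. The same doubt applies to mir-3158-1 at 2.52 (2.24 to 2.82) and mir-3158-2 at 3.52 (3.21 to 3.87), in the DPCD gene. Next came mir-4717 at 3.11 (2.40 to 4.01), which rested on 16 and 125 counts and had only 35 reads in the larger pooled stacks, mir-129-2 at 2.75 (2.64 to 2.86), mir-550b-2 at 2.59 (2.32 to 2.88) and mir-138-1 at 2.52 (2.39 to 2.65). Both miR-129 and miR-138 are best known from the nervous system. The hairpins mir-129-2 and mir-138-1 lie at chr11:43602939-43603039 and chr3:44155724-44155792, and each has a copy elsewhere in the genome. The precursor mir-550b-2 also has a copy, mir-550b-1 at 2.47, and copies of the lettered relative mir-550a were at 2.32 to 2.52. No pooled stack carried the name of mir-550b-2, so a partner on the opposite strand could not be looked for. Its counts may therefore not be its own.

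The lowest log2 ratio was that of mir-4521 at −2.74 (−3.50 to −2.11), from 163 and 21 counts, in a stack at chr17:8090149-8090345 that also carries the annotation of a tRNA-Ser gene. It was followed by mir-548h-5 at −2.54 (−3.55 to −1.74), which rested on 89 and 13 counts, is 1 of 5 copies and had 2 reads in the pooled stacks. Next came mir-2114 at −2.48 (−3.28 to −1.80), mir-124-3 at −2.29 (−2.52 to −2.08) and mir-215 at −1.77 (−2.04 to −1.52). The list closed with mir-19b-2 at −1.49 (−1.55 to −1.43), a copy with 450 reads in the pooled stacks against 2462278 over mir-19b-1 and its neighbour mir-92a-1, mir-144 at −1.48 (−2.12 to −0.91) and mir-362 at −1.45 (−1.62 to −1.28). Both copies of mir-19b were thus at least 2-fold lower in AGO3, though the counts may not be their own.

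Of the precursors at least 2-fold apart, 25 of the higher and 12 of the lower have another copy or a partner on the opposite strand, so that their counts may be split arbitrarily. With no minimum on counts the number at least 2-fold apart was 436 of 1038, and among precursors with at least 1000 counts it was 54, or 24.4% of them.

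**Figure D1:**
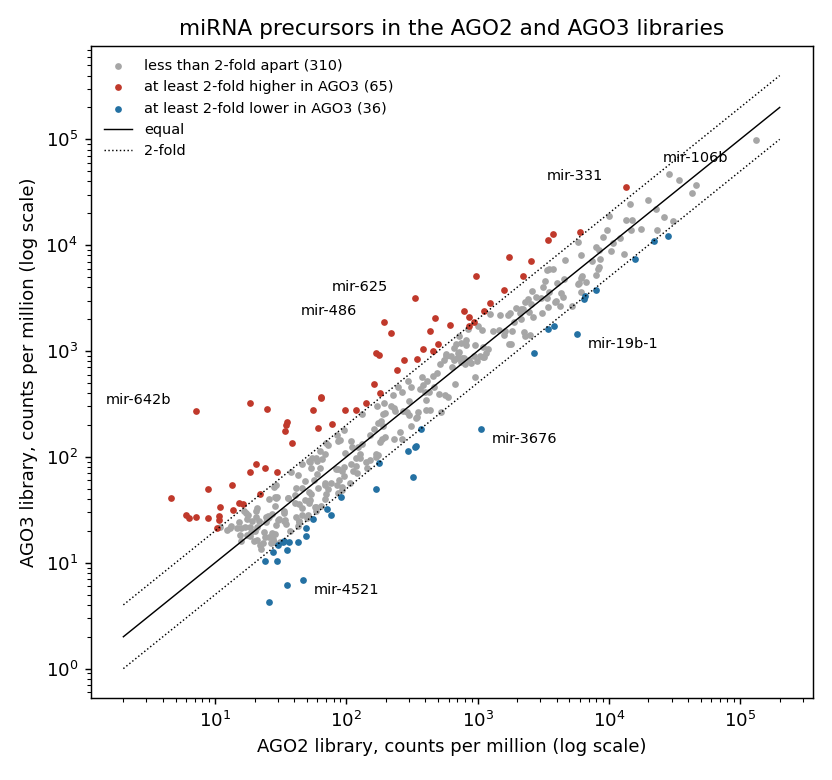
CPM (counts per 1000000) of the miRNA precursors with at least 100 counts, in the AGO2 library (x axis) and the AGO3 library (y axis), both on log scales, 1 point per precursor. The solid line marks equal levels and the dotted lines a 2-fold difference; 65 points lie on or above the upper dotted line and 36 on or below the lower one.

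The second comparison asked how alike the whole profiles were. The precursor with the most counts was the same in both libraries. In AGO2, mir-106b, which lies in an intron of the DNA replication gene MCM7 (chr7:99691597-99691709), took 13.3% of the counts, and in AGO3 it took 9.81%, a log2 ratio of −0.44 (−0.44 to −0.43). Of the 10 most abundant precursors, 5 others were also lower in AGO3: mir-15b (−0.87), mir-20a (−0.50), mir-18a (−0.45), mir-27b (−0.31) and mir-10a (−0.06). The other 4 were higher in AGO3: mir-331 (1.38), mir-126 (0.70), mir-615 (0.40) and mir-33a (0.27). Only mir-331 among these 10 was at least 2-fold apart, with 1.36% of AGO2 and 3.54% of AGO3 counts at chr12:95702199-95702298. The pooled stacks ranked them otherwise. Of these 10, 4 were also among the 10 with the most stack reads over 273 precursors compared, whereas mir-27b ranked 31, mir-126 ranked 32 and mir-331 ranked 37. The hairpin of mir-33a lies in the sterol regulator gene SREBF2, that of mir-126 in EGFL7 and that of mir-615 within the HOXC cluster.

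Together these 10 precursors held 39.8% (39.8 to 39.9) of the AGO2 counts and 37.4% (37.3 to 37.5) of the AGO3 counts. Across precursors with at least 100 counts, Pearson's r of log2(CPM + 1) was 0.948 and Spearman's rho was 0.935; precursors are not independent replicates. Of 1038 precursors with any count, 875 were counted in both libraries, 91 in AGO2 alone and 72 in AGO3 alone. None of those counted in a single library had more than 16 counts.

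The next comparison asked whether miRNA families moved together. The miR-15/16 family, whose members repress cell cycle genes, was lower in AGO3 in 8 of 8 precursors, and miR-221 and miR-222, which repress the cell cycle inhibitor p27, were higher in AGO3 in 2 of 2. These precursors are not independent of each other. In the genome mir-15a lies beside mir-16-1, mir-15b beside mir-16-2, mir-195 beside mir-497, mir-424 beside mir-503 and mir-221 beside mir-222, and the copies of mir-16 may share reads. The miR-15/16 family held 9.29% (9.26 to 9.32) of the AGO2 counts and 5.36% (5.33 to 5.38) of the AGO3 counts. Its precursors mir-15a at chr13:50623262-50623350 and mir-16-1 were at least 2-fold lower, mir-15a at −1.21 (−1.23 to −1.20), while mir-15b was at −0.87 (−0.89 to −0.85), mir-16-2 at −0.47 (−0.50 to −0.44) and mir-424 at −0.31 (−0.33 to −0.30). The median of the family was −0.56, at percentile 1.95 of 10000 random lists of the same size and abundance, and at percentile 3.26 of random lists drawn from all precursors past the minimum, which is inside 2.5 to 97.5. For mir-222 the log2 ratio was 1.46 (1.42 to 1.50) and for mir-221 0.84 (0.79 to 0.90), with a median of 1.15 at percentile 92.4. Percentiles describe these 2 libraries only. Random lists drew each precursor separately, so they lack any likeness of neighbours and copies within a family. With 19 lists, a list can also fall outside 2.5 to 97.5 through the number of lists alone.

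The miR-30 family had a median of −0.45 at percentile 2.42, or 9.46 of random lists drawn from all precursors past the minimum, but its summed counts made up 0.92% of AGO2 and 0.909% of AGO3, a log2 ratio of −0.02. Its most abundant members went both ways, with mir-30e at 0.50, mir-30a at 0.19, mir-30d at −0.27 and mir-30b at −0.71. When the copies of mir-30c were added up the median was −0.27 at percentile 5.36. The let-7 family, the regulators of developmental timing, had a median of −0.29 at percentile 5.09, whereas the sum of its 12 precursors was higher in AGO3, at 0.11. The copies of let-7a, which give the same main miRNA, differed: let-7a-1 stood at 0.40, let-7a-3 at 0.87 and let-7a-2 at −0.76. Another precursor, let-7f-1, was at −1.10. In the pooled stacks let-7a-2 had 2 reads, and no stack carried the name of let-7a-1 or let-7a-3. The stacks therefore cannot show to which copy the counts of let-7a belong, and these counts may be split arbitrarily. The precursor let-7f-1 had far fewer stack reads than its copy let-7f-2. Stack reads of copies can depend on how reads that match both were placed, so they cannot show to which copy the counts belong. The counts of let-7f-1 may not be its own.

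The growth-promoting miR-17~92 cluster and its paralogues held 27.5% of AGO2 and 22.5% of AGO3 counts. Of its 15 precursors, 1 was at least 2-fold higher in AGO3 (mir-363, 1.28) and 2 were at least 2-fold lower (mir-19b-1 and mir-19b-2), and the median was −0.22 at percentile 22.5. Neighbours on chromosome 13 differed in sign, with mir-17 at 0.76 (0.74 to 0.78) beside mir-18a at −0.45 and mir-20a at −0.50.

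The following families also had medians between percentiles 2.5 and 97.5 of random lists. The precursors of the HOX clusters had a median of 0.21 at percentile 71.4, with mir-196a-1 at 1.21, mir-196b at 0.21, mir-10b at 0.04 and mir-10a at −0.06. With median-of-ratios scaling mir-10b turned to −0.04. In the pooled stacks mir-196a-1 had 7602 reads against 227211 for its copy mir-196a-2. As for let-7f, this cannot show to which copy the counts belong, and those of mir-196a-1 may not be its own. The miR-181 family had a median of 0.43 at percentile 74.7, led by mir-181a-1 at 1.45 and mir-181c at 1.14, with mir-181a-2 at 0.82 and mir-181b-1 at −0.12. In the miR-29 family the median of 0.16 at percentile 63.1 joined mir-29b-1 at 1.60 and mir-29b-2 at 0.75 with mir-29a at −0.42 and mir-29c at −0.63. The summed log2 ratio of miR-29 and its median with copies summed were both −0.42, opposite in sign to its median over single precursors. The miR-23/27/24 clusters had a median of −0.04 at percentile 36.6, with mir-27a at 0.23, mir-27b at −0.31, mir-23b at −0.41 and mir-23a at −0.59. Its highest members were mir-24-1 at 0.79 and mir-24-2 at 0.56, and with copies summed the median was −0.31 at percentile 12.9.

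**Figure D2:**
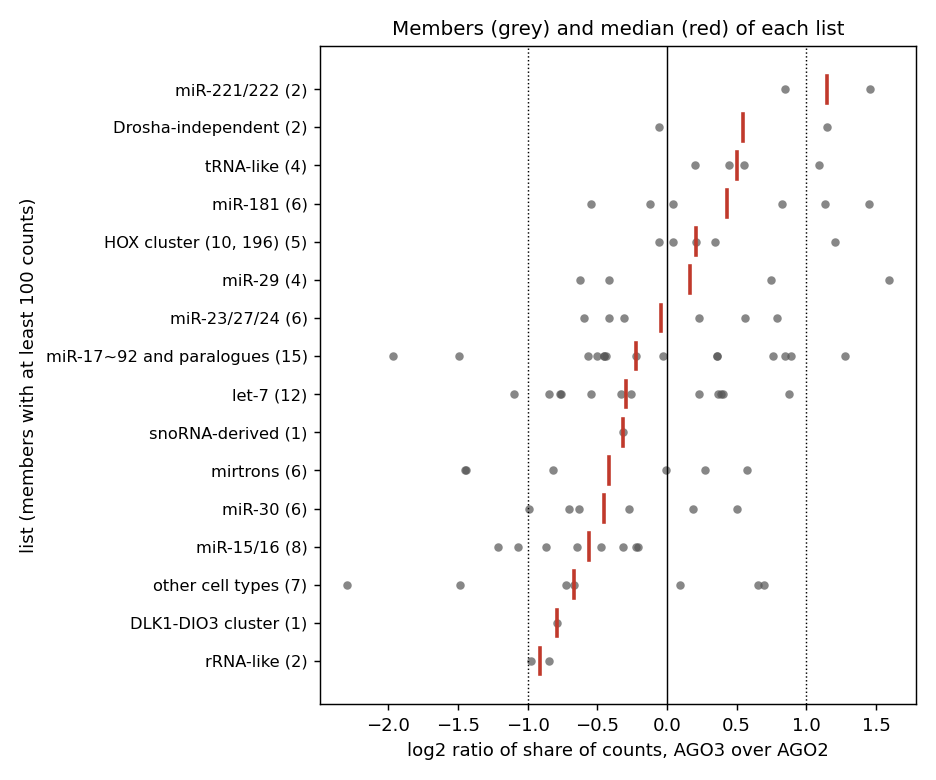
Log2 ratio of the share of counts, AGO3 over AGO2 (x axis), of the precursors with at least 100 counts in each list (y axis, number of such precursors in brackets). Grey points are precursors, red bars are list medians and dotted lines mark 2-fold; all 8 points of miR-15/16 lie below 0 and both points of miR-221 and miR-222 above it.

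A further comparison took miRNAs that are made in unusual ways, since the series concerns Dicer and its substrates. The erythroid mir-451a, which is cut by AGO2 itself without Dicer, had 3 counts in AGO2 and 1 in AGO3, and mir-451b had 2 and 0; at this depth no ratio can be given. The Drosha-independent precursors were mir-320a, higher in AGO3 at 1.15 (1.13 to 1.18), and mir-484 at −0.06 (−0.08 to −0.04); their median was 0.55 at percentile 75.2. Mirtrons are in general spliced introns, but how each entry of the mirtron list is made was not tested. The list had 6 precursors past the minimum and a median of −0.41 at percentile 17.3. Its summed counts were nevertheless higher in AGO3, at 0.25 (0.18 to 0.31). The median was 0.13 at percentile 54.6 with a minimum of 20 counts and −0.01 at percentile 41.9 with copies summed. Of the 6, 2 were at least 2-fold lower, mir-1229 in MGAT4B at −1.45 (−1.92 to −1.01) and mir-1236, from 150 and 48 counts, at −1.45 (−1.95 to −0.98), while mir-877 was at 0.57, mir-1227 at −0.01 and mir-1228 at −0.82.

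Entries of the tRNA-like list took 0.207% of AGO2 and 0.369% of AGO3 counts. Those past the minimum were higher in AGO3 in 4 of 4, with mir-1260a at 1.09 (1.03 to 1.15), mir-4454 at 0.56, mir-1260b at 0.44 and mir-720 at 0.20, and a median of 0.50 at percentile 70.6. The list did not hold mir-3676 and mir-4521, which lie at −2.53 and −2.74. With both added, an alternative chosen after seeing the data, 4 of 6 were higher in AGO3, the median was 0.32 at percentile 60.0, and the summed log2 ratio went from 0.83 to 0.28 (0.25 to 0.32). The stack over mir-1260a (chr14:77732569-77732596) carried 0.999 edits per read, that is, differences from the reference. The rRNA-like mir-3648 and mir-3687 were at −0.84 and −0.97, a median of −0.91 at percentile 10.3, and shared 1 stack. The single snoRNA-derived precursor past the minimum, mir-664, was at −0.32 (−0.67 to 0.03), a difference within counting error, at percentile 47.8.

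Markers of cells other than kidney line cells were also compared. The list had 7 precursors past the minimum and a median of −0.66 at percentile 5.41, or 2.33 of random lists drawn from all precursors past the minimum, but its sum was higher in AGO3, at 0.67, because mir-126 held most of its counts. This endothelial miRNA took 2.89% of AGO2 and 4.69% of AGO3 counts. The neuronal precursors mir-124-3, mir-124-1 and mir-124-2 stood at −2.29, −0.73 and −0.66. With copies of one miRNA added up the median of the list was 0.09, and with a minimum of 20 counts it was 0.20. The pluripotency miRNAs of the miR-302 and miR-371 clusters summed to 9 counts in AGO2 and 5 in AGO3, and those of the placental cluster on chromosome 19 to 47 and 57. The imprinted DLK1-DIO3 cluster summed to 402 and 153 counts, a log2 ratio of −1.20 (−1.48 to −0.93). Its only precursor past the minimum, mir-376c, was at −0.79 (−1.33 to −0.27), at percentile 22.3; the 6 precursors with at least 20 counts had a median of −1.22 at percentile 0.74.

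The last comparison described small RNAs outside miRNAs, from stacks of overlapping reads over the genome. The stacks pool libraries and do not separate AGO2 from AGO3. They held 68649476 reads in 502547 stacks, 6.05 times the reads of both libraries above, more than those libraries can give if each read was counted once. Precursors of miRNAs took 77.1% (77.07 to 77.09) of these reads, and tRNA genes 13.9% (13.87 to 13.88). The tRNA reads came mostly from 3 places: a tRNA-Val gene with anticodon TAC at chrX:18692998-18693116 with 6347216 reads, a tRNA-Ile gene with anticodon TAT at chr6:27599178-27599374 with 1064393 reads and a tRNA-Thr gene with anticodon AGT at chr19:33667946-33668082 with 692310 reads. The first of these held 66.6% of all tRNA reads and 40.3% of all reads outside miRNA precursors.

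Reads outside miRNA precursors made up 22.9% of the total, 15736680 reads. Sites between genes or in repeats took 2.36% of all reads, introns 1.95%, sites antisense to genes 1.41%, exons of other genes 1.12%, mitochondrial RNA 1.07% and ribosomal RNA 0.621%. Small nucleolar and Cajal body RNAs took 0.199%, and 71.9% of their reads were on SCARNA15 (chr15:83424757-83424825, 98317 reads). Vault RNAs took 0.165%, with 84758 reads on VTRNA1-2 and 19598 on VTRNA1-1, Y RNAs and related scRNAs 0.109%, spliceosomal snRNAs 0.0454% and 7SL RNA 0.000859%.

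Besides the tRNA genes, the stacks with the most reads outside miRNA precursors were an rRNA repeat on an unplaced contig with 420636 reads and a mitochondrial stretch from the rRNA genes to MT-CO3 with 339406. They were followed by 5 short sites with at least 0.9 edits, or differences from the reference, per read. These were an intergenic site at chr8:12511894-12511916 with 278403 reads and 0.9997 edits per read, an intergenic site at chr12:130494591-130494615 with 142882 reads and 0.9997 edits per read, and a site in an intron of the chromatin remodelling gene SMARCC1 (chr3:47722808-47722837) with 140326 reads and 0.941 edits per read. The remaining pair lay antisense to introns of LINGO2 (chr9:28024799-28024826, 131239 reads, 0.9998 edits per read) and of the elastin gene ELN (chr7:73470435-73470462, 120386 reads, 0.964 edits per read). The mapping quality class in the stack list was UNIQ10_K0 for the sites on chromosomes 12 and 9. For the sites on chromosomes 8, 3 and 7 it was UNIQ40_K0. Among stacks of 20 to 24 bases in width the share outside miRNA precursors was 95.4%; stacks wider than 24 bases held 99.8% of the reads on miRNA precursors.

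**Figure D3:**
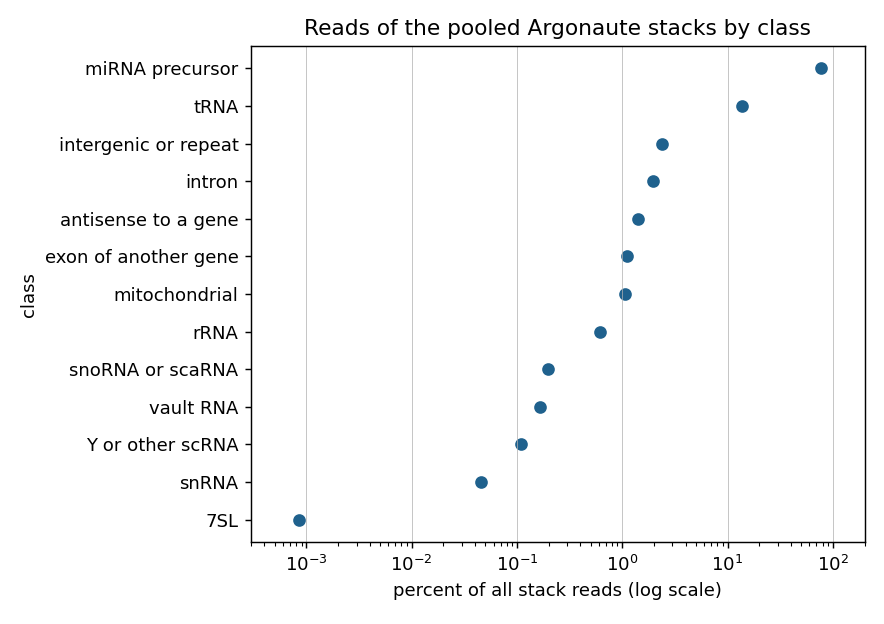
Percent of the 68649476 pooled stack reads (x axis, log scale) in each class of annotation (y axis), 1 point per class. Counting intervals are narrower than the points; miRNA precursors took 77.1% and tRNA genes 13.9%.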

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

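The tests in this part were chosen after the results were seen. Reads outside the main measurement gave 2 signals. Stacks on the strand opposite to a miRNA precursor held 6800 reads in 300 stacks, 0.00991% of all stack reads. Stacks that also lie over a precursor on their own strand were left out of this count. The 4353 reads of mir-642a, opposite mir-642b, are thus not among them. The 6800 reads are more than the 3 that a count of 0 allows, a limit that a few stray or misplaced reads would pass. Stacks with at least 1000 reads and at least 0.9 edits per read, in introns, between genes or antisense to genes, held 1792254 reads.

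The edited stacks were 113 of 239 such stacks, 47.3% (40.8 to 53.8), against 3 of 321 stacks over miRNA precursors (0.935%), namely mir-1260a, mir-1304 and mir-7977. Variants of the cell line against the reference were taken to predict at most 10% of stacks and like rates in all classes, and these shares argue against them as the whole cause. Reads that come from elsewhere and were placed with a mismatch remain a candidate explanation for the 113 stacks, which cannot be told apart from true transcripts here because no reference sequence was used. No biological explanation was tested.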

How the results depend on the processing

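Alternatives named as added were chosen after seeing the data. The 101 precursors at least 2-fold apart (65 higher, 36 lower in AGO3) became 105 with median-of-ratios (61 and 44) or TMM scaling (60 and 45), which lower every log2 ratio by 0.08 and 0.10, and 97 with a pseudocount of 5. They became 184 (115 and 69) with a minimum of 20 counts, 54 (38 and 16) with 1000 and 436 (242 and 194) with none. Other numbers of precursors enter at these minimums, and the share apart was 28.8% with 20, 24.4% with 1000 and 42.0% with none. Counting intervals beyond 2-fold left 20 lower. Added: 64 (40 and 24) without precursors that have a copy or antisense partner, 50 (36 and 14) without those whose number another precursor has, 90 with copies summed and 100 without mir-106b. Pearson's r was 0.961 with a minimum of 20 and 0.905 with 1000, and rho was 0.906 with 1000; the cause was not tested. Each library's own top 10 held 41.6% of AGO2 and 38.2% of AGO3 counts, higher by construction. Lists outside percentiles 2.5 to 97.5 numbered 2 (miR-15/16 and miR-30), 3 with a minimum of 20 counts (with DLK1-DIO3 at 0.74), and 1 (miR-15/16) with copies summed; with random lists from all precursors miR-15/16 (3.26) and miR-30 (9.46) dropped out and the count was 1, the other cell types at 2.33 (both added). Reads outside miRNA precursors, and tRNA as a share of them, went from 22.9% and 60.5% to 22.1% and 63.4% in stacks of at least 10 reads and 95.4% and 0.165% at widths of 20 to 24. Added: 15.1% and 33.8% without the largest tRNA stack, 20.3% and 70.0% without stacks of at least 0.9 edits per read. Of 74 named precursors none called apart changed sign, and 2 crossed the 2-fold line with TMM scaling. Arm use, its alternatives and lists limited to the more abundant arm were not run, since arms are not named. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible. Depth limits precursors under 100 counts.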

Other observations

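The cluster test below was set before its result was seen, and the other tests in this part were chosen after the results were seen. Copies of one miRNA often differed in their ratio. Of 37 miRNAs with at least 2 copies past the minimum, 13 had copies at least 2-fold apart and 11 had copies of opposite sign, with a median difference of 0.65 on the log2 scale. The brain-enriched miR-128 had mir-128-1 at 1.68 and mir-128-2 at −0.07, miR-7 had mir-7-1 at 1.28 and mir-7-2 at −0.77, and mir-103b-1 stood at −0.38 beside mir-103b-2 at 2.17. No stack was named for either copy of mir-103b, so that partners on the opposite strand could not be looked for. The counts of the mir-103b copies may therefore not be their own. Copies give the same main miRNA, but their other arms can differ, and the arms were not separated.

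Some neighbouring precursors also differed, though the median difference between neighbours was 0.45 on the log2 scale against 0.77 for random pairs. Of 36 pairs of neighbours within 10 kb on one strand, with no copy or antisense partner by name, 9 were at least 2-fold apart. The share of random pairs that far apart was not computed. The widest was mir-331 at 1.38 beside mir-3685 at −1.17, and let-7e at 0.37 lay beside mir-125a at 1.53.

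The 101 precursors at least 2-fold apart were set against technical and biological explanations. Reads shared between precursors recognisable by name were not the whole cause: 64 of 310 precursors with no numbered copy or antisense partner were at least 2-fold apart, 20.6% (16.3 to 25.6), against 37 of 101 (36.6%) of the others, and so were 50 of 218 whose number no other precursor has, lettered or not, 22.9% (17.5 to 29.1). Sharing between differently numbered precursors was not tested. Different expression of whole transcription units in the cell cultures may contribute. The median difference between neighbours was 0.45 on the log2 scale against 0.77 for random pairs, a ratio of 0.577, as low in 0.7% of random draws. Resampling the pairs gave 0.48 to 1.06, which leaves it open. Some precursors, such as mir-18a, are in more than 1 pair of neighbours. Random pairs shared no precursor and the resampling took pairs as independent, so the 0.7% and the resampled range are approximate. The 3′ adapter, with 1 library for each sequence, cannot be told apart from the protein, and preferential loading of AGO3 or AGO2 stays open and untested.

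The precursor counts and the pooled stacks ranked miRNAs differently. Over 273 precursors with no numbered copy, antisense partner or shared stack, 4 of the 10 with the most counts were among the 10 with the most stack reads, and r of the log2 values was 0.837. The hairpin mir-19a had 36880 counts and 4358877 stack reads, whereas mir-27b had 273175 counts and 326189 stack reads. A constant factor from the larger number of pooled reads is argued against by the spread, as the log2 ratio of stack reads to counts had an SD of 2.21 and was below 0 for 14 precursors; the SD was 2.07 over the 198 whose number no other precursor has. A different make-up of the pooled libraries or different alignment settings were not tested, and the ratio was unrelated to the AGO3 over AGO2 ratio (r = −0.01 across precursors).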
